A study of Mus musculus with 7 samples.

How the data were processed

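Total RNA was extracted from myoblasts of C57BL/6 wild type and Hmga2 KO mice, and biotin-labelled cRNA was prepared for Affymetrix arrays, per the labels' protocols. The values the authors deposited are probe set intensities on a linear scale, 1 column per sample for 45101 probe sets of a mouse genome expression array. Each array has a median intensity of 150, so the authors scaled the arrays to a common median. The summarization method, the background correction and the software are not given in the sources used here, and no detection call was used. The lowest intensities, 33.2 to 36.7, act as a floor, so folds of dim genes are understated.

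Intensities were transformed to log2(intensity + 1) with no further normalization, and fold changes are on that scale. Probe sets were named through the platform annotation table. Of the probe sets, 34958 were paired with 1 gene, 932 with several and 9160 with none in that table, besides 64 controls. For 34754 probe sets the gene identifier was found among RefSeq genes of assembly GRCm38.p6, which changed 0 symbols, and 204 kept the symbol of the table. That assembly was used for names and for the order of neighbouring genes, and no coordinates are given because the array table names no build. Probe sets of several genes were left out. Each of 18193 genes was represented by its probe set with the highest mean over the 7 samples.

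Samples were grouped by their titles into wild type (3) and Hmga2 KO (4). Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The model had no covariate, since the design text names none. Sex is unevenly spread over the groups, so a model with sex and a comparison of the 5 females served as alternatives. Male and female Hmga2 KO samples were compared in a 3-group fit of all 7 samples. The level of Hmga2 was also tested by exact permutation over the 35 splits of the samples.

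Gene lists were written before the data were examined. They hold 946 genes, of which 886 were measured, in 28 lists with at least 5 measured members. Lists were tested with limma's camera at its preset correlation of 0.01, which compares the members with all other genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Members past the test are counted over all genes and adjusted over the list alone. Genes beside Hmga2 were tested with Fisher's exact test.

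The named genes follow a rule set before the data were examined. It takes a fixed set of genes tied to Hmga2 and to myoblasts, and in each direction the 12 largest changes past the threshold with groups that do not overlap, leaving out Xist and Y-linked genes. Where fewer than 5 pass in a direction, it takes the 5 with the smallest p. It also takes up to 4 members with the smallest p of each list past camera, and up to 10 genes past the sex comparison. Part of the fixed set is not reported here. Not every gene that the rule allows for a list is given.

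The alternatives were sex as a covariate, females alone, the replicate number as a block, leaving out each sample, equal medians, quantile normalization, leaving out the dimmest 40% of genes, the mean or the most variable probe set of a gene, a trended and robust prior, array weights, a pseudocount of 16, a minimum fold of 2 and an adjusted p of 0.1. For neighbours, 25 and 100 genes on each side were also used. The scripts were tested on simulated data. In 5 simulations of the Hmga2 KO comparison, 200 of 18193 genes were changed, all drawn from outside the dimmest 40%. Of these, 45.1% of genes changed 1.5-fold, 79.1% changed 2-fold and 97.3% changed 4-fold were recovered, with 5.34% false calls. For male against female Hmga2 KO samples, over the same 18193 genes, these shares were 8.36%, 57.9% and 90.3%. Changes of dim genes were not tried in either, and with fewer changed genes the adjustment is stricter. The shares can therefore overstate what is recovered from the real data. A simulated list shift of 0.3 was found in 5 of 5 simulations, with 1 other list past the test. The simulated genes varied independently of each other, whereas members of the sarcomere list had an estimated correlation of 0.81. The simulation therefore does not show how often camera at its preset correlation calls lists whose members vary together.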

Results

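Gene expression was measured on 7 Affymetrix Mouse Genome arrays, each hybridised with biotin-labelled cRNA from the myoblasts of C57BL/6 mice. Myoblasts are the precursor cells that fuse into skeletal muscle fibres. The design compared 4 samples from mice without Hmga2 (Hmga2 KO) with 3 wild type samples, and so asked which transcripts depend on this gene. The wild type samples were all female, whereas Hmga2 KO replicates 1 and 3 were male and replicates 2 and 4 female. Each array had a median intensity of 150 and a lowest value between 33.2 and 36.7. Across genes, which are not independent replicates, the log2 values of the 21 pairs of samples correlated at 0.985 to 0.994 within a group and at 0.980 to 0.993 between groups. Their median absolute log2 difference was 0.145 to 0.235, so no pair held the same values. The ratio of the 3' to the 5' Actb control probe set, a sign of RNA integrity, was 1.94 in wild type replicate 2 and 1.61 to 1.74 in the other 6 samples. For Gapdh this ratio was 1.52 in wild type replicate 2 and 1.22 to 1.36 in the other 6. The labels call the samples biological replicates, and their number limits the precision of every value below.

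The targeted gene was examined first. Hmga2, a chromatin protein that binds AT-rich DNA and is abundant in embryonic and precursor cells, was among the bright transcripts of wild type myoblasts and near background in all 4 Hmga2 KO samples. On its brightest probe set the intensity was 11599 ± 1443 (SD, n = 3) in wild type and 95.8 ± 7.70 (SD, n = 4) in Hmga2 KO, a 119-fold difference. On another 2 probe sets the mean fell from 10606 to 53.4 and from 8214 to 54.8, levels of background. The remaining, dim probe set had means of 59.0 in wild type and 43.9 in Hmga2 KO (adjusted p = 0.311, limma). For comparison, 9 probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty gave 33.9 to 58.2 in the 5 female samples, which lack these genes, so that of the 3 bright probe sets only the brightest stayed above this range in Hmga2 KO. Against the top of this range, the other 2 fell at least 178-fold and at least 137-fold. The gene-level change was -6.90 on the log2 scale (SE 0.115, adjusted p = 1.00e-08, limma). The exact two-sided permutation p was 0.0286, the smallest that the 35 splits of these samples can give. Where the deleted part lies relative to the probe sets is not given in the sources used here.

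Beyond Hmga2, 4 genes passed the test between Hmga2 KO and wild type, and in each of them every Hmga2 KO sample lay on the same side of every wild type sample. Lmcd1, a LIM-domain cofactor expressed in muscle, fell from a mean log2 value of 8.69 ± 0.12 (SD, n = 3) to 7.15 ± 0.15 (SD, n = 4), with a change of -1.54 (SE 0.113, adjusted p = 0.00239, limma). Zdbf2, an imprinted gene with a zinc finger domain, fell from 10.81 to 9.29, by 1.52 on the log2 scale (adjusted p = 0.00782). Sp6, a transcription factor of the Sp family, rose from 7.41 to 9.12 on its brightest probe set (change 1.71, SE 0.180, adjusted p = 0.0240). Ces2g, a carboxylesterase, rose from 9.64 to 10.86 (change 1.22, SE 0.131, adjusted p = 0.0240). The 3 dimmer probe sets of Sp6 differed by 0.05, 0.08 and -0.01.

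**Figure D1:**
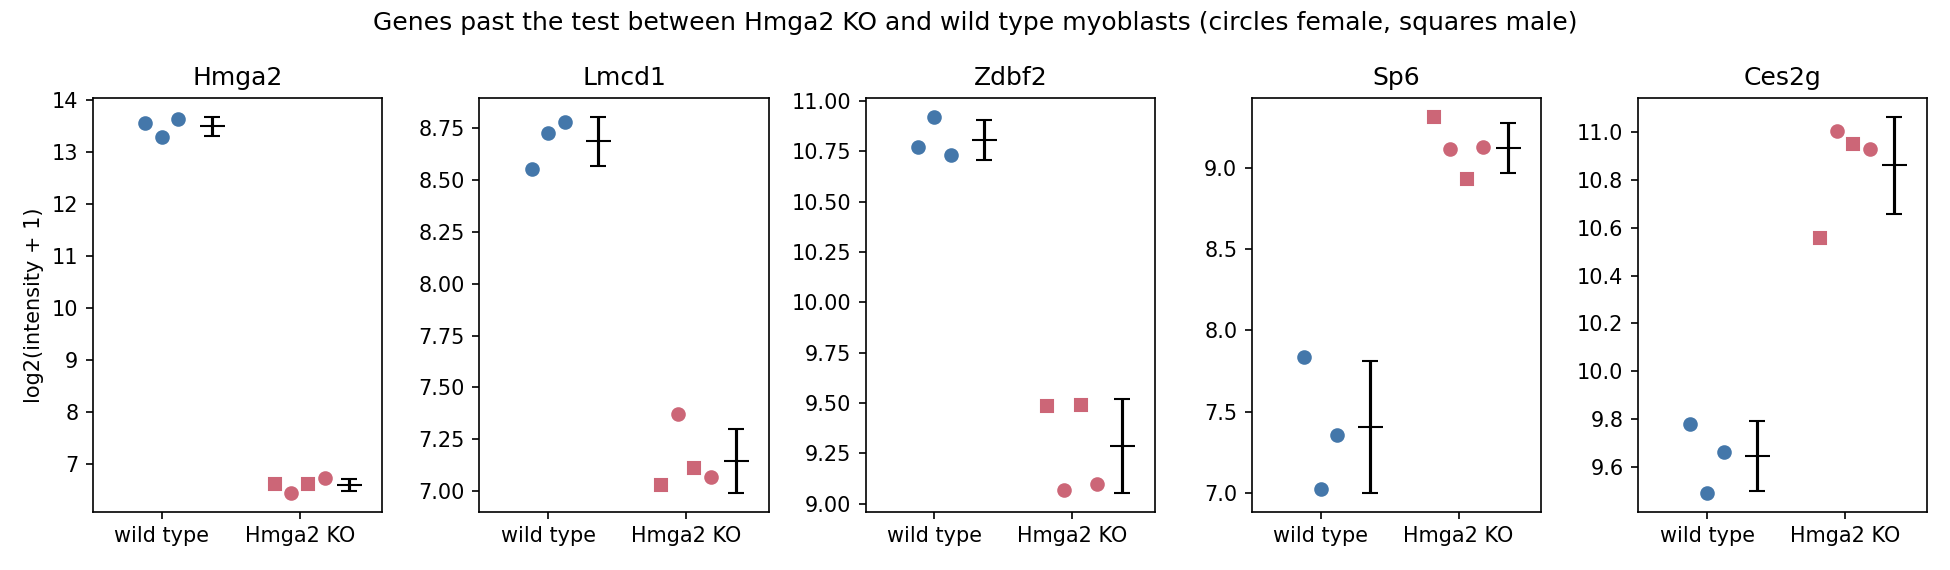
Log2(intensity + 1) of the 5 genes past the test in each of the 3 wild type and 4 Hmga2 KO samples, one panel per gene, each panel with its own vertical scale. Points are samples, with females as circles and males as squares, and the bars give the mean and SD of the group. The groups do not overlap in any panel, and Hmga2 lies between 13.29 and 13.64 in wild type and between 6.44 and 6.72 in Hmga2 KO.

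Of 18193 genes tested with limma, 5 passed an adjusted p of 0.05, of which 2 were higher and 3 lower in Hmga2 KO. Without adjustment, 2423 genes (13.3%) had a p under 0.05 where chance alone would give 910. Of these, 1879 lay below and 544 above the median change of all genes, which was -0.07. With sex in the model 1345 genes had such a p, and in females alone 1246, closer to the 910. Fewer samples bear on the genotype in these 2 fits. The groups did not overlap for 2122 genes (11.7%), against 5.71% by chance. The count past the adjusted threshold was 3 without wild type replicate 1 and 2 without wild type replicate 3. It was 3 without Hmga2 KO replicate 3 and 17 without Hmga2 KO replicate 2. With sex in the model 4 genes passed, 3 of them shared and the other Krtap19-3 (higher in Hmga2 KO, change 1.28, adjusted p = 0.0395), and Sp6 (adjusted p = 0.0954) and Ces2g (adjusted p = 0.0529) did not. Sp6 and Ces2g also missed the threshold without wild type replicate 3 (adjusted p = 0.241 for both), as did Zdbf2 (adjusted p = 0.0777).

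Several genes with large differences did not pass. Eya2, a transcriptional coactivator, had mean log2 values of 7.81 in wild type and 9.55 in Hmga2 KO (adjusted p = 0.0879). Lipo3, of the acid lipase family, had 8.40 and 9.43 (adjusted p = 0.0898), and Gclm, the modifier subunit of the first enzyme of glutathione synthesis, 11.01 and 11.70 (adjusted p = 0.158). Among the smallest p-values in the other direction were Clybl, a mitochondrial lyase, with 9.20 and 8.28 (adjusted p = 0.0624) and Fhod3, a formin of the sarcomere, with 9.08 and 8.23 (adjusted p = 0.0877). None of these groups overlapped. Without Hmga2 KO replicate 2, Eya2 and Clybl passed (adjusted p = 0.0339 for both), and Clybl also with array weights (adjusted p = 0.0436). Clybl passed too when each gene's probe sets were averaged (adjusted p = 0.0474). It has 1 probe set, so its own values stayed the same there and only those of other genes changed.

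Genes tied to Hmga2 or to myoblast identity were chosen before the data were examined, and none of the 18 measured besides Hmga2 passed by limma, while 2 had an unadjusted p under 0.05. Those 2 were Cdkn2b, an inhibitor of cyclin-dependent kinases, with mean log2 values of 10.04 in wild type and 10.87 in Hmga2 KO (adjusted p = 0.194), and Igf2bp3, an RNA-binding protein, with 10.86 and 10.23 (adjusted p = 0.354). Igf2bp3 had 10.68 in male and 9.79 in female Hmga2 KO samples, so that its difference from wild type was -1.07 in females alone (adjusted p = 0.249). The muscle regulators were bright in both groups, with 12.44 and 12.54 for Pax7, 13.91 and 13.85 for Myod1, 14.23 and 14.06 for Myog, and 13.39 and 12.98 for Mef2c. The Mef2c difference of -0.41 was -0.06 in females alone, since Hmga2 KO males had 12.63 and Hmga2 KO females 13.33. Myf5 had 10.63 and 11.27, with an SD of 0.70 among the Hmga2 KO samples. In the growth factor axis, Igf2 had 13.28 and 13.08, Igf1r 11.89 and 12.01, and Igf2bp1 6.58 and 6.61. Myc had 10.74 and 10.54, Sp1 11.63 and 11.76, Junb 10.45 and 10.50, and Lin28b, close to background, 5.51 and 5.57. Among cell cycle genes, Ccnd1 had 13.38 and 13.19, Mki67 11.60 and 11.46, Cdkn1a 13.42 and 13.24, and Cdkn2a 11.69 and 11.39.

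Gene lists were then compared as groups. Genes of the sarcomere, the respiratory chain and cell division lay lower in Hmga2 KO than other genes, and genes of the extracellular matrix and of fibroblasts lay higher. By camera with its preset correlation, 17 of 28 lists passed, 7 lower and 10 higher. None passed with an estimated correlation, where the smallest adjusted p was 0.150 and 4 lists had an unadjusted p under 0.05. The estimated correlation was 0.81 for the sarcomere list, 0.62 for the respiratory chain, 0.59 for G2/M and 0.54 for G1/S, against the preset 0.01. For the fibroblast list it was 0.0069, for Wnt genes 0.0020 and for TGF-beta and BMP genes -0.0038, all below the preset value. Members varying together therefore do not account for the loss of those calls. Where the estimated correlation is high, the p at the preset correlation is too small. The members of such a list are then not independent in the counts that follow. Exact permutation of the list means, a test chosen after the data were seen, gave 0 lists after adjustment, which 28 lists and a smallest p of 0.0286 leave little room to pass, and 1 without it, the HMGA list that holds Hmga2 itself. Except for Hmga2 itself, no member of any list passed over all genes.

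The sarcomere and terminal differentiation list stood lowest, with 46 of its 47 members below the median of all genes and a list median 0.56 below it on the log2 scale (camera adjusted p = 2.48e-09). Its adjusted p = 0.414 with an estimated correlation. Adjusted over the list alone, 1 member was lower and 0 higher. Myh8, a perinatal myosin heavy chain, had mean log2 values of 10.63 in wild type and 9.29 in Hmga2 KO (adjusted p = 0.212), Tcap 9.41 and 8.42 (adjusted p = 0.269), Casq2, the calcium store protein of the sarcoplasmic reticulum, 12.90 and 11.98 (adjusted p = 0.293), and Actn3 10.76 and 9.66 (adjusted p = 0.293). In females alone the differences were -0.52 for Tcap and -0.50 for Casq2, against -0.99 and -0.92 over all samples. The list mean, relative to the mean of all 7 samples, was 0.07, 0.69 and 0.34 in the wild type samples. The 0.69 belongs to wild type replicate 2, which had the highest 3' to 5' ratio of Actb. In Hmga2 KO the list mean was -0.98 in replicate 1, 0.31 in replicate 2, -0.32 in replicate 3 and -0.12 in replicate 4. Hmga2 KO replicate 2 thus lay within the wild type range. In females alone the list median lay 0.19 below that of all genes (camera adjusted p = 1.96e-04), and without Hmga2 KO replicate 1 it lay 0.31 below (camera adjusted p = 3.96e-07).

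Of the mitochondrial respiratory chain list, 55 of 57 members lay below the median of all genes (camera adjusted p = 2.48e-09, and adjusted p = 0.412 with an estimated correlation). Adjusted over the list alone 0 members passed by limma, and 23 had an unadjusted p under 0.05, all lower. Ndufs8, a subunit of complex I, had mean log2 values of 11.27 and 10.87, and Uqcrc1, of complex III, 12.17 and 11.75. Of the hypoxia and glycolysis list, 23 of 34 members lay below the median (camera adjusted p = 0.00496, and adjusted p = 0.385 with an estimated correlation). Adjusted over the list alone, 8 members were lower and 1 higher. Pfkp, a phosphofructokinase, had 9.98 and 9.14, Pdk1 11.26 and 10.62, Ndrg1 9.44 and 8.99, and the glucose transporter gene Slc2a3 the opposite order, 7.63 and 8.09.

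Cell division genes lay lower as well. In the G1/S and DNA replication list, 45 of 47 members lay below the median of all genes (camera adjusted p = 7.80e-09, and adjusted p = 0.385 with an estimated correlation), and 3 were lower when adjusted over the list alone. Cyclin E1 (Ccne1) had mean log2 values of 10.79 and 10.25, Rfc5 9.74 and 9.26, Pola2 8.93 and 8.52, and Chaf1b 8.43 and 7.94. In the G2/M list, 53 of 62 members lay below (camera adjusted p = 1.06e-04, and adjusted p = 0.555 with an estimated correlation), and 0 passed over the list alone, while 13 had an unadjusted p under 0.05. Among them Mybl2 had 8.08 and 7.66, and Aurkb 10.60 and 10.28. Of ribosome biogenesis and MYC target genes, 35 of 40 lay below (camera adjusted p = 9.07e-04, and adjusted p = 0.501 with an estimated correlation), and 0 passed over the list alone, with 7 at an unadjusted p under 0.05. Dkc1 had 12.36 and 12.03, and Rrp12 9.73 and 9.26. The list of HMGA and other architectural chromatin proteins passed (camera adjusted p = 0.0280, and adjusted p = 0.448 with an estimated correlation), but without Hmga2 its camera adjusted p was 0.266. Hmgb3 had 11.67 and 11.32. Without wild type replicate 3 the G2/M call ended (camera adjusted p = 0.103) and the G1/S median moved from -0.22 to -0.14 against that of all genes (camera adjusted p = 4.02e-05).

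**Figure D2:**
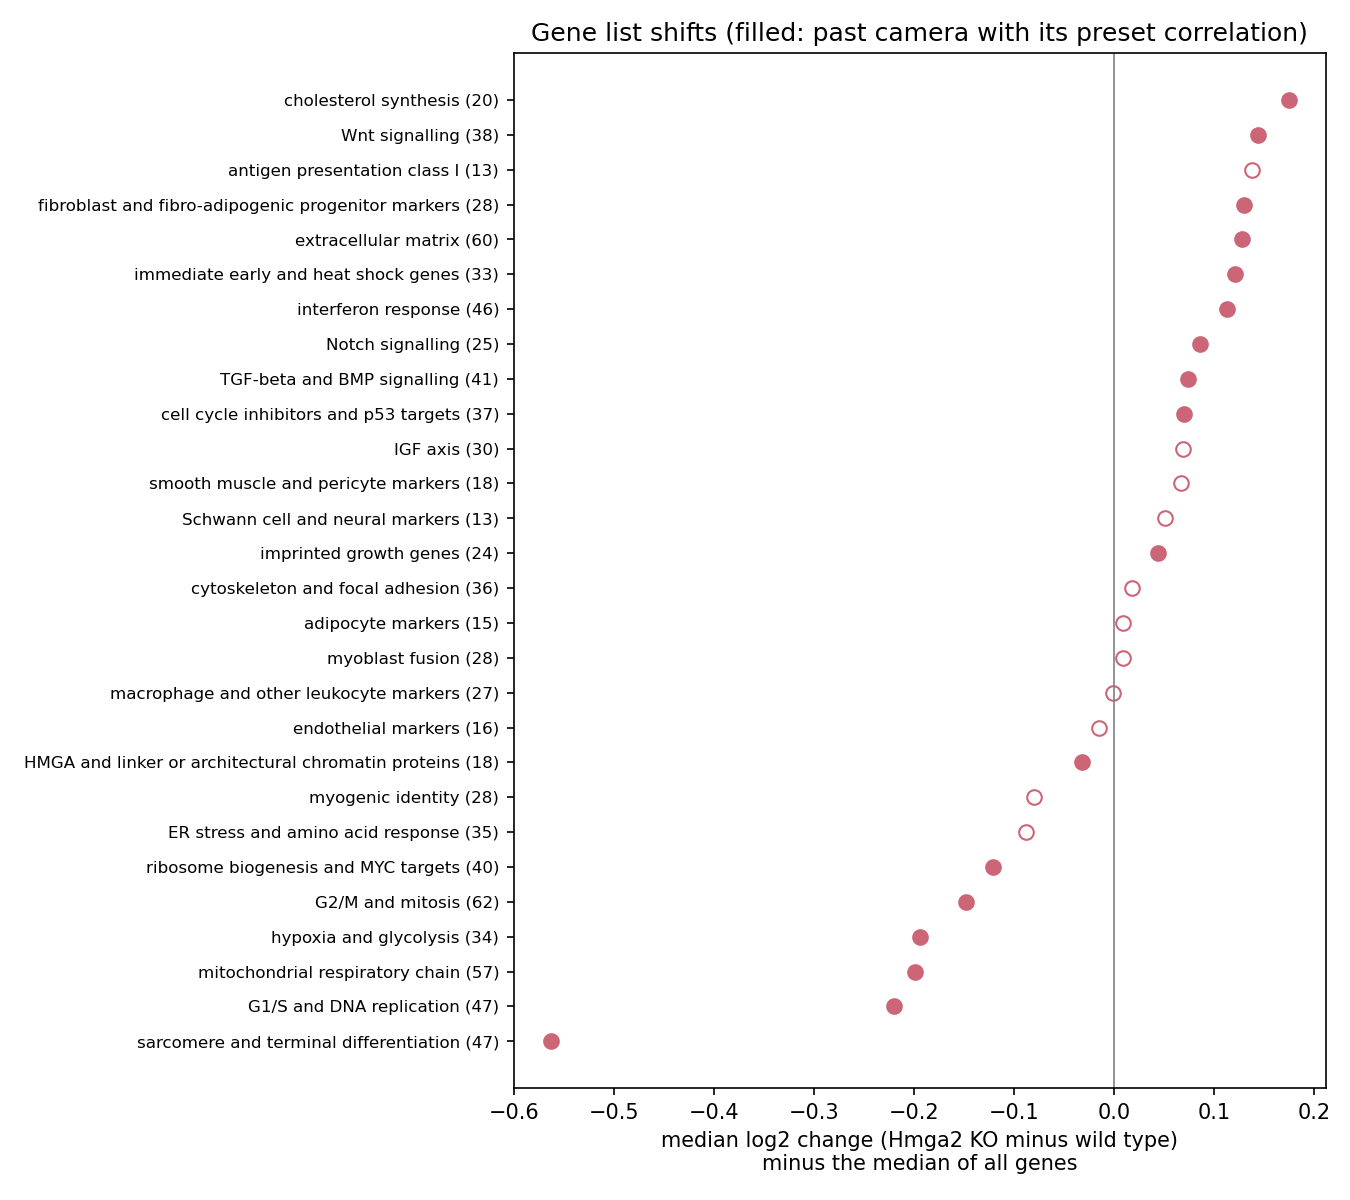
Median log2 change of each of the 28 gene lists between Hmga2 KO and wild type, minus the median change of all genes, with the number of measured members in brackets. Filled points passed camera with its preset correlation and open points did not. The sarcomere list lies at -0.56, and the other lists lie between -0.22 and 0.17.

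Matrix genes lay higher. In the extracellular matrix list, 47 of 60 members lay above the median of all genes (camera adjusted p = 3.12e-05, and adjusted p = 0.269 with an estimated correlation), and 1 was higher when adjusted over the list alone. Vcan, a large proteoglycan, had mean log2 values of 11.58 and 12.25 (adjusted p = 0.189), Thbs2 9.92 and 10.96, and Lox, which cross-links collagen, 9.36 and 10.71 (adjusted p = 0.340). In females alone Thbs2 differed by 0.56 and Lox by 0.66, against 1.04 and 1.35 over all samples. The list mean was 0.37 in Hmga2 KO replicate 1 and -0.16 to 0.07 in the other 3 Hmga2 KO samples, against -0.17 to -0.00074 in wild type. The call ended in females alone (camera adjusted p = 0.166) and with sex in the model (camera adjusted p = 0.117).

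Markers of fibroblasts and fibro-adipogenic progenitors, another cell type of muscle, lay higher with the matrix genes and opposite to the sarcomere genes. Of 28 markers, 23 lay above the median (camera adjusted p = 3.18e-05, and adjusted p = 0.150 with an estimated correlation), and 2 were higher when adjusted over the list alone. The matrix list holds 9 of these markers too, and of the other 19 markers 16 lay above the median. Mgp had mean log2 values of 11.42 and 12.16 (adjusted p = 0.158), Smoc2 6.60 and 8.27 (adjusted p = 0.201), and Islr 9.96 and 10.76 (adjusted p = 0.293). Dcn had 5.89 and 6.21, Lum 5.78 and 5.82, and Dpt 5.60 and 5.61, all close to background in both groups. Lum and Dpt were chosen after their values were seen. Without Hmga2 KO replicate 4, Smoc2 passed (adjusted p = 0.0239).

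Lists of other cell types did not pass camera. Their adjusted p was 0.0659 for Schwann cell and neural markers, 0.181 for smooth muscle and pericyte markers, 0.185 for adipocyte markers, 0.751 for macrophage and other leukocyte markers, and 0.934 for endothelial markers. Adjusted over the list alone, 1 smooth muscle marker was lower and 2 adipocyte markers were higher, and none of the Schwann, leukocyte and endothelial markers passed by limma, with 1, 0 and 0 at an unadjusted p under 0.05. The adipocyte list passed as higher without wild type replicate 1 (camera adjusted p = 0.0475) and the smooth muscle list without wild type replicate 2 (camera adjusted p = 0.0490).

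**Figure D3:**
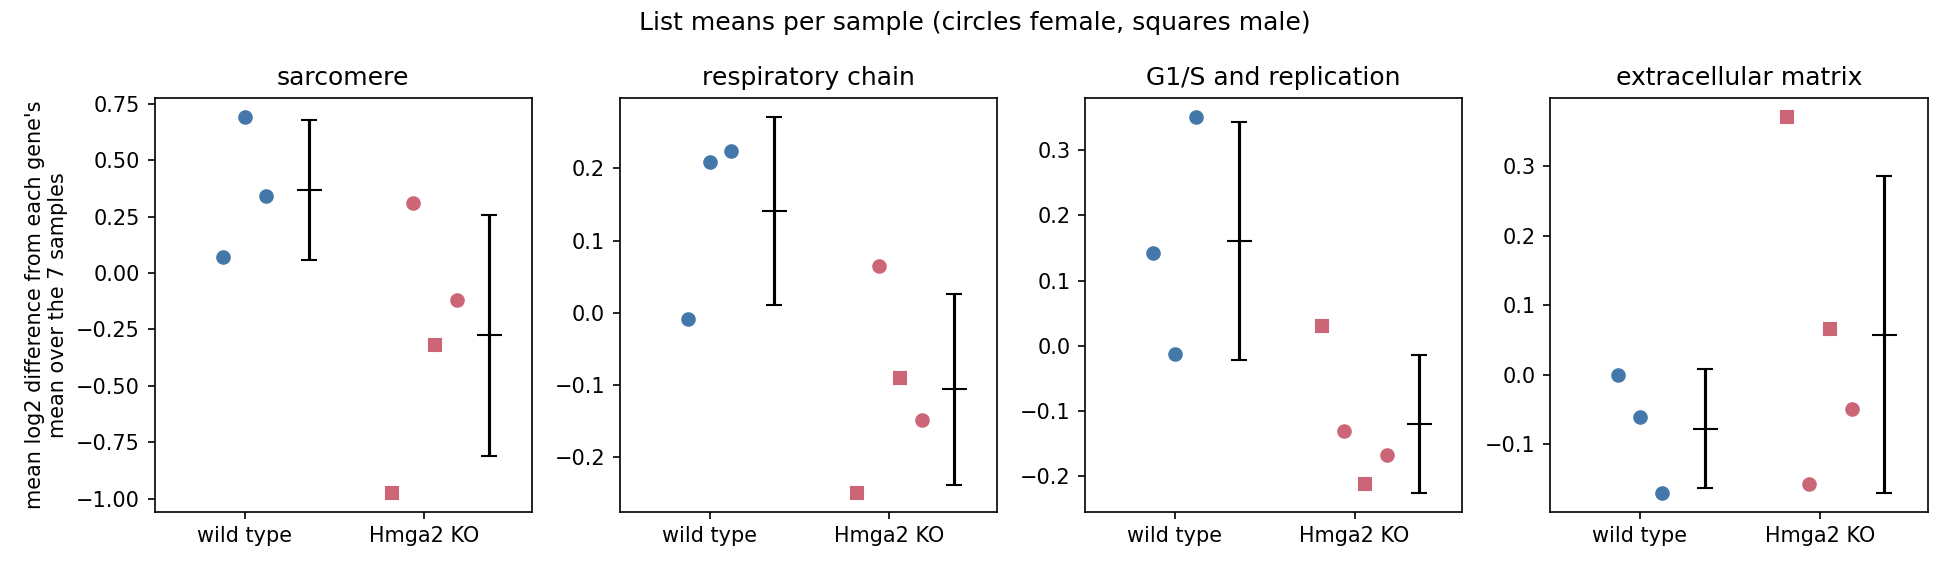
Mean of 4 gene lists in each sample, as the log2 difference from each gene's mean over the 7 samples, one panel per list with its own vertical scale. Points are samples, with females as circles and males as squares, and the bars give the mean and SD of the group. In the sarcomere panel Hmga2 KO replicate 1 lies at -0.98 and replicate 2 at 0.31, within the wild type values.

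Regulatory and metabolic lists made up the rest of those higher in Hmga2 KO, with list medians 0.04 to 0.17 above that of all genes. Of cell cycle inhibitors and p53 targets, 23 of 37 lay above the median (camera adjusted p = 7.84e-04, and adjusted p = 0.249 with an estimated correlation), and 3 were higher when adjusted over the list alone. Btg2, an antiproliferative gene that the immediate early list also holds, had mean log2 values of 10.78 and 11.53 (adjusted p = 0.201), Pmaip1 12.31 and 12.73, and Fas 7.96 and 8.40. The list's own median change was -0.0014 and its mean 0.07, so the 2 differed in sign. Of interferon response genes, 32 of 46 lay above (camera adjusted p = 9.07e-04, and adjusted p = 0.280 with an estimated correlation), yet the members with the smallest p went both ways, with 7.06 and 7.62 for Samd9l and 9.36 and 8.86 for Ifit2. Of cholesterol synthesis genes 16 of 20 lay above (camera adjusted p = 9.57e-04, and adjusted p = 0.293 with an estimated correlation). Sc5d had 9.01 and 9.34. Of immediate early and heat shock genes 23 of 33 lay above (camera adjusted p = 0.00341, and adjusted p = 0.269 with an estimated correlation), with 11.99 and 12.46 for Nr4a2 and 8.56 and 8.18 for Socs3.

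Signalling lists followed. Of Wnt genes 26 of 38 lay above the median (camera adjusted p = 0.00496, and adjusted p = 0.173 with an estimated correlation), with mean log2 values of 9.62 and 10.85 for Wnt5a and 9.82 and 10.47 for Fzd4. Of TGF-beta and BMP genes 26 of 41 lay above (camera adjusted p = 0.00741, and adjusted p = 0.173 with an estimated correlation), with 10.34 and 10.95 for Id4 and 6.36 and 7.20 for Ltbp2. Of Notch genes 18 of 25 lay above (camera adjusted p = 0.0300, and adjusted p = 0.412 with an estimated correlation), with 9.31 and 10.27 for the ligand gene Jag1 (a difference of 0.51 in females alone) and 12.38 and 12.18 for Rbpj. Of imprinted growth genes 13 of 24 lay above (camera adjusted p = 0.0145, and adjusted p = 0.385 with an estimated correlation). Their own median change was -0.03 and their mean 0.11, while against the median of all genes, as in the test, the list median was 0.04 higher. Meg3 and Rian, non-coding RNAs of 1 imprinted domain, had 10.72 and 11.80, and 12.53 and 13.12, and Nnat had 8.22 and 9.20. Adjusted over the list alone, 1 immediate early gene was higher and no member of the interferon, cholesterol, Wnt, TGF-beta, Notch or imprinted lists passed by limma, with 5, 1, 4, 5, 3 and 7 members at an unadjusted p under 0.05. In females alone the cholesterol list (camera adjusted p = 0.40) and the immediate early list (camera adjusted p = 0.0755) no longer passed, nor did TGF-beta genes with sex in the model (camera adjusted p = 0.0579). Without wild type replicate 3 the immediate early (0.276), TGF-beta (0.136) and Notch (0.441) calls ended as camera adjusted p. Without Hmga2 KO replicate 2 (0.147) or 3 (0.0687) the Notch call ended as well, and imprinted genes lost theirs without Hmga2 KO replicate 2 (0.0987) or 3 (0.0653).

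The remaining lists did not pass camera, with an adjusted p of 0.163 for ER stress and amino acid response, 0.220 for the insulin-like growth factor axis, 0.224 for class I antigen presentation, 0.503 for myoblast fusion, 0.702 for cytoskeleton and focal adhesion, and 0.702 for myogenic identity. Adjusted over the list alone, the class I list had 1 member lower, the myogenic identity list had 1 higher and 1 lower, and the ER stress, growth factor, fusion and cytoskeleton lists had none by limma, with 4, 4, 3 and 5 members at an unadjusted p under 0.05. The ER stress list passed as lower without wild type replicate 3 (camera adjusted p = 0.0231) or without Hmga2 KO replicate 3 (camera adjusted p = 0.0235).

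Male and female Hmga2 KO samples were compared because both sexes occur in that group alone. Genes of the Y chromosome separated them, with mean log2 values of 12.10 in males and 5.77 in females for Eif2s3y (adjusted p = 7.08e-07, limma), 10.30 and 5.30 for Kdm5d, and 9.18 and 5.14 for Uty. Xist, the RNA that silences 1 X chromosome in females, was 6.86 in males and 12.83 in females, and the levels of these genes matched the labelled sex in all 7 samples. Besides them, Cpne8, a copine, was higher in male (8.77) than in female Hmga2 KO samples (6.03), which lay near female wild type samples (6.09, adjusted p = 0.00206 between the sexes). Glrp1 had 8.77 in male and 7.15 in female Hmga2 KO samples and 7.70 in wild type (adjusted p = 0.0206). Krtap19-3, a keratin-associated protein gene, had 6.03 in male and 7.41 in female Hmga2 KO samples (adjusted p = 0.0260), and the female wild type samples, at 6.13, lay with the males. In the 4 Hmga2 KO samples alone, Cpne8 passed (adjusted p = 0.00252) and Glrp1 and Krtap19-3 did not (adjusted p = 0.163 for both). In all, 7 genes passed and 1146 had an unadjusted p under 0.05. With 2 samples of each sex, these values rest on few animals, and the test pooled the spread over all 7 samples.

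Genes next to Hmga2 on chromosome 10 were examined because DNA around a targeted allele can come from another mouse strain. None of the 100 nearest measured genes, 50 on each side, passed by limma, against 4 of 18044 elsewhere. With so few genes past the test, Fisher's exact test could show no difference (odds ratio interval 0 to 276). Of these 100 genes, 12 had an unadjusted p under 0.05, no larger a share than the 13.3% of all genes. Of the 12, 10 were higher and 2 lower, whereas over all genes 544 with such a p lay above and 1879 below the median change. Lrig3 had mean log2 values of 8.38 in wild type and 9.12 in Hmga2 KO (adjusted p = 0.227), Irak3, an inhibitor of Toll-like receptor signalling, 6.55 and 7.16 (adjusted p = 0.227), and Lemd3, of the inner nuclear membrane, 11.99 and 12.36 (adjusted p = 0.269). Lrig3, Irak3 and Lemd3 were chosen after their values were seen.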

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

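The test of probe sets without a listed gene was chosen only after the data were seen. In Ces2g, past the test between Hmga2 KO and wild type, Hmga2 KO replicate 1 had a log2 value of 10.56 while the other 3 Hmga2 KO samples lay at 10.93 to 11.00. Its gap to the others was 0.838 of the range, above the critical value of 0.829. Within the Hmga2 KO samples it was the only one of 123 gene and list values so far from its group, where chance alone would give 6.15. Wild type groups, of 3 samples, also held gaps of such a share, as in Mfng (log2 values 7.36, 7.35 and 7.92).

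Among the 9160 probe sets without a listed gene, which the comparisons of named genes leave out, 9 passed the test between male and female Hmga2 KO samples, 8 of them higher and 1 lower in males. The brightest had a mean intensity of 72146 in male Hmga2 KO samples, against 556 in female Hmga2 KO and 292 in wild type samples, whose highest value was 422 (adjusted p = 7.92e-04, limma). Its value in Hmga2 KO replicate 1, 105395, was the highest on any of the 7 arrays. No explanation was tested for it.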

How the results depend on the processing

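The permutation of list means, the HMGA list without Hmga2 and the neighbours at an unadjusted p under 0.01 were chosen after the data were seen. The fall of Hmga2 kept its direction and passed in all 18 alternatives (log2 change -7.61 to -5.53), as did that of Lmcd1 (-1.62 to -1.45). Zdbf2 passed in 16 of 18, Ces2g in 12 and Sp6 in 11, with no change of sign. Lmcd1, Zdbf2 and Ces2g have 1 probe set each, so the alternatives on probe sets left their values as they were. The count of 5 genes was 9 at an adjusted p of 0.1 and ranged from 2 to 17 when 1 sample was left out. The cause of the 17 genes without Hmga2 KO replicate 2 was not tested.

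Replicate numbers 1 to 3 occur in both groups. Over genes, deviations of same-numbered samples from their group means correlated at 0.359, 0.432 and -0.157, and samples 1 and 2 of each group correlated best with their own number while sample 3 did not. Whether a number marks something shared by the samples thus differs between the numbers, and what it might be was not tested. With the replicate number as a block, 99 genes passed (35 higher, 64 lower), and 1 neighbour of Hmga2 passed in place of 0. All 5 genes and Eya2, Lipo3, Clybl and Fhod3 were among the 99. So were Cdkn2b of the fixed set (adjusted p = 0.0381, limma) and the list members Btg2, Thbs2, Lox, Smoc2, Pfkp, Meg3, Myh8 and Tcap. Hmga2 KO replicate 4 has no wild type partner, so this fit rests on replicates 1 to 3.

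The 17 lists past camera became 0 with an estimated correlation and 0 by permutation of list means (where the smallest p of 0.0286 leaves little room after adjustment). By fry, which tests a list against no change rather than against other genes, 1 list passed for 1 direction (the HMGA list, which holds Hmga2) and 4 for either direction. Neighbours at an unadjusted p under 0.01 numbered 7. The sex comparison called 3 genes without the dimmest 40%, since 4 of the 7 genes (Uty, Kdm5d, Cpne8 and Krtap19-3) belong to that part and are not tested there, and 5 to 8 when 1 sample was left out, where Cpne8 always passed but Glrp1 and Krtap19-3 only without wild type replicate 2. Among named genes, 1584 results kept their side of the threshold, 18 moved past it, 15 fell short of it and 15 without a call changed sign. Among lists, the counts were 431, 6 and 21, and 15 without a call changed their direction by camera, which the list median need not follow. Setting the medians equal changed nothing, since they were equal already. Signal near the array floor limits dim genes such as Lum, Dpt and Lin28b.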

Other observations

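Of the tests in this part, those on single samples, cultures, fibroblasts, sex and DNA of another strain were chosen only after the results they address were seen. For single samples and sex, the criterion was redrawn several times. Passing camera at its preset correlation argued against both for the sarcomere list, and an estimated correlation left both open but was void because no list passes it. Keeping at least 80% of the shift without Hmga2 KO replicate 1 or in females alone argued against both for G1/S and G2/M, but that sample did not carry these shifts. Asking in addition for list means of the groups that do not overlap left only sex for G1/S argued against, but for single samples this could not be met. The test of single samples used here leaves out the sample that shrinks a shift most and asks whether at most 20% of it is left or at least 80%, past camera. That of sex asks whether males and females differ within Hmga2 KO by as much as the whole group difference needs. Transcription factor genes that mark body position were not described above. Of 95 measured, none passed by limma and 10 had an unadjusted p under 0.05. Irx2 had mean log2 values of 9.25 in wild type and 8.58 in Hmga2 KO, Tbx15 12.07 and 11.51, Hoxa11 9.93 and 9.55, and Meis1 6.93 and 7.31, all 4 chosen after their values were seen. The hypothesis that the groups came from muscles of different position was tested on all 95. The odds ratio of an unadjusted p under 0.05 against other genes was 0.765 (95% interval 0.354 to 1.48, Fisher's exact p = 0.544), under the bound of 1.5 set beforehand. By that rule the whole list argued against the hypothesis. Dim genes reach such a p less often, however (13.3% of all other genes did, and 16.9% of those with a mean log2 value over 8). Among the 38 listed genes over 8 the odds ratio was 0.922 (95% interval 0.315 to 2.24), past that bound. The rule set beforehand did not apply the bound to this subset. Since the subset could not meet it, the question was left open, with too few such genes expressed to tell.

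In the number of genes past the test, 2 of the 35 splits of the 7 samples gave 5 genes or more, the real split included. The highest of the other splits also gave 5, and it placed Hmga2 KO replicate 2 with the wild type samples. That split still sets Hmga2 KO replicates 1, 3 and 4 against all wild type samples, so it keeps most of the group contrast. Every remaining split gave 0 genes. By the count alone, chance cannot be excluded. It does not speak to Hmga2 itself, whose change was the same in direction and past the test in 18 of 18 alternatives.

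The lower sarcomere and cell division lists and the higher matrix list were weighed by what remained of each median shift against all genes and by list means. The intervals for sex and the splits of the samples used list means, from which the change of all genes (median -0.07) was not subtracted. For G1/S, male minus female Hmga2 KO samples was 0.058 in the list mean (95% interval -0.373 to 0.490). This interval ended short of the -0.561 that sex would need. The needed value was taken as exact, however. The group difference behind it is itself uncertain with so few samples, so sex as the whole source is not excluded. In females alone the G1/S median was -0.28 (main value -0.22). For the other lists sex cannot be told apart from the genotype either, because with so few samples the interval reached the difference needed. The difference was -0.011 for G2/M (95% interval -0.470 to 0.448, needed -0.396), -0.743 for the sarcomere list (-1.73 to 0.241, needed -1.29) and 0.322 for the matrix list (-0.038 to 0.681, needed 0.270). In females alone the G2/M median stayed at -0.15, past camera, while the sarcomere median shrank from -0.56 to -0.19 and the matrix median from 0.13 to 0.067. A single sample as the source cannot be told apart by the bounds used here. Without the sample whose loss shrank a shift most, the part left lay between 20% and 80% for each list. It was 63.9% for G1/S, 55.8% for the sarcomere list and 71.2% for the matrix list, so no sample carried most of these median shifts. For G2/M it was 43.5%. The matrix list mean, however, rested largely on Hmga2 KO replicate 1, at 0.37. The other Hmga2 KO samples had -0.16 to 0.066, against -0.17 to -0.00074 in wild type. Without wild type replicate 3 the G1/S median was -0.14 and the G2/M median -0.064, the latter no longer past camera, and without Hmga2 KO replicate 1 the sarcomere median was -0.31 and the matrix median 0.091. Variation between cultures whatever the genotype may account for these shifts, since of 35 splits 4 gave a difference in list mean as large for the sarcomere list (exact permutation p = 0.114), 3 for G1/S (p = 0.0857), 4 for G2/M (p = 0.114) and 15 for the matrix list (p = 0.429), as may an effect of Hmga2. More fibroblasts in the Hmga2 KO cultures stays open too. Against the median of all genes, 100% of the 6 abundant markers, 2 of them on the matrix list as well, lay higher (exact 95% interval from 54.1%). That interval treats markers measured in the same 7 samples as independent, so it holds no spread between cultures. The rise was carried by Islr (0.87), Lox (1.42) and Mgp (0.80), while Gsn (0.08), Tcf7l2 (0.14) and Col3a1 (0.19) hardly differed. Lum stayed at background.

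More p-values under 0.01 than elsewhere lay next to Hmga2, a cutoff chosen after the data were seen. At an unadjusted p under 0.05 by limma there was no excess, with 12 of the 100 nearest genes against 13.3% of all genes. Of the 25 genes on each side, 6 of 50 had an unadjusted p under 0.01 (12%) against 3.33% of other genes (odds ratio 3.95, 95% interval 1.37 to 9.36, Fisher's exact p = 0.00632), 5 of them higher in Hmga2 KO. Chance clustering cannot be told apart, since 1.21% of windows of 50 genes held as many but 7.14% of windows of 100 genes did. With 50 and 100 genes on each side the odds ratio was 2.18 (Fisher's exact p = 0.0512) and 1.52 (Fisher's exact p = 0.230). DNA of another strain around the targeted allele may be a source of these differences, as may an effect of the deletion on its neighbours, and the odds ratio of 3.95 does not separate them.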
